A study of Mus musculus with 12 samples.

How the data were processed

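RNA was measured in the cortex of 12 mice that had received no treatment, 3 in each combination of age (3 or 10 months) and genotype label (TAU58/2 transgenic or non-transgenic control), on a C57Bl/6 background. Per the labels' protocols, RNA was extracted with a column-based tissue kit and turned into strand-specific libraries after depletion of ribosomal RNA. Groups, ages and replicate numbers were taken from the sample labels. Libraries are named here by age, label and replicate number.

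The deposited values are FPKM per gene and library, in tables made by the authors, a separate file for each age, each holding 48526 genes. Per the submitters' processing notes, HISAT2 2.0.4, SAMtools, StringTie 1.3.0 and R 3.4.2 were used with mouse genome builds mm10 and GRCm38. The order and options of these steps and the gene annotation are not given in the sources used here. The FPKM totals differ between libraries, so the deposited values do not share a common total. The authors' tables also hold mean FPKM per group, a fold change (a ratio of transgenic over control), its log2 value, and p-values with q-values; which test gave these is not stated per the file headers, and they are quoted only where named as the authors' deposited table. No read counts were used here. Values of genes near the detection limit fell on steps in part of the genes (between 10.1% and 15.0% of the low genes of a library against the 10-month control 1 library). From these steps, the relative depth of the other libraries ranged from 1.07 to 1.37 times that of the 10-month control 1 library. The absolute depth is unknown, so no counting interval or detection floor is given. Genes that other libraries list at high levels are listed at exactly 0 in some libraries, so such a value is reported only as listed at 0.

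Gene names were taken from the tables, and gene types and coordinates from the GENCODE annotation of GRCm38, in which 468 of the IDs had no location. FPKM were analysed as log2(FPKM + 0.1). Genes with a mean of at least 1 FPKM in at least 1 of the 4 groups were tested, 9846 in all. A linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust), so that all groups shared an estimate of the spread. Both tables entered the same fit, on the untested assumption that their values are per-library FPKM with no scaling within a table. Contrasts were the genotype effect at 10 months, the genotype effect at 3 months, their difference (the age by genotype interaction), and the age effects within each genotype label. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and 0.05 was the threshold. Every fold change is on the log2(FPKM + 0.1) scale, which understates changes of low genes, and where all libraries of a group are listed at 0 any log2 value printed is set by the pseudocount and is no measure of size. Effects averaged over both ages or over both genotype labels were added after the data were seen. Mapt and Thy1 were also compared with a two-sided exact permutation test of 3 against 3 libraries, for which 0.1 is the smallest possible p. Calls at the 2 ages were compared with Fisher's exact test.

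Before the data were examined, 41 gene lists with 515 distinct genes were fixed, covering cortical cell types, glial states, pathways of tau and inflammation, and other tissues that a dissection could include. All of the list genes matched a name in the tables. The 35 lists with at least 3 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, each with Benjamini-Hochberg adjustment over lists. Members were adjusted over all genes tested and over the list alone. Part of the genes named in the text were set by a rule that was also fixed then. For each genotype comparison it took up to 8 genes per direction with the largest change among those past the threshold whose groups did not overlap, up to 4 members with the smallest p of each list past the threshold, and Mapt and Thy1. For the interaction and the age effects it took up to 4 genes per direction. The rule passed over predicted genes, and those named here were chosen after their values were seen. Other genes outside the rule, among them Gjb1, Tapbp, H2-Q4, Axl, Spp1, Egr2, C1qc and Alad, were also named after their values were seen.

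Alternatives fixed at the same time were other pseudocounts (1 and 0.01), no filter beyond a value above 0 in at least 3 libraries, a filter at 5 FPKM, size factors, quantile normalization, the replicate number as a block, eBayes without trend and robust, weights per library, a limit of 0.58 on the log2 fold change, each age fitted alone, and leaving out each library in turn. Robust regression, and setting to missing those values that lay far under a gene's median, were added after the data were seen. Label splits were redrawn with fixed seeds. Shared sequence between genes was counted as the percentage of a gene's 31-base words found in another annotated transcript.

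The fit was tested on simulated data for the 10-month genotype comparison over 9846 genes, 200 of them changed. With each gene's own residuals shuffled over the libraries, 4% of the genes changed by 1 on the log2 scale and 42% of those changed by 3 were recovered, with 50 calls of which 4 were false. With normal noise of 0.2 times each gene's residual SD, 75% and 99% were recovered, with 181 calls of which 7 were false. Of 20 simulated unchanged lists, camera called 0. The noise was drawn for each gene separately, so the simulation held no correlation between genes. It therefore does not test camera's error rate where genes are correlated. Tables were handled with the R package data.table (version 1.17.8) and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.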

Results

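Gene expression was compared in the cortex of 12 mice, of which 6 were labelled as carrying the TAU58/2 transgene and 6 as non-transgenic controls. TAU58/2 mice express human tau with the P301S mutation, a cause of inherited frontotemporal dementia, from a neuronal Thy1 promoter. Each genotype was sampled at 3 and at 10 months of age, with 3 animals per group. The design asks which genes differ with the transgene at each age, whether that difference changes with age, and how expression changes with age in each genotype. Values are FPKM, fragment counts scaled to transcript length and library size, as deposited. The libraries summed to between 125933 and 158077 FPKM and listed between 12828 and 13914 genes above 0. The depth of the other libraries ranged from 1.07 to 1.37 times that of the 10-month control 1 library, and the absolute depth is unknown. Within a group, log2 values of 2 libraries correlated across genes with a Pearson r between 0.664 and 0.743, against 0.662 to 0.741 for libraries of different groups, and no pair was identical. Of 4390 genes with a median of at least 5 FPKM, each library listed between 91 and 226 below an eighth of the gene's median, the most in the 10-month transgenic 3 library.

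Mapt, the mouse tau gene, and Thy1, whose promoter drives the transgene, were examined first, since transgene fragments can only be counted under mouse genes. At 3 months both were higher in the libraries labelled transgenic than in every control library. Mapt (chromosome 11, 104231390 to 104332090, plus strand, GRCm38) was at 46.1 ± 2.48 FPKM in the libraries labelled transgenic and 8.70 ± 2.88 FPKM in control libraries (SD, n = 3). Thy1 (chromosome 9, 44043384 to 44048579, plus strand) was at 422 ± 16.1 against 120 ± 18.6 FPKM (SD, n = 3). The log2 fold changes were 2.44 (SE 0.85) for Mapt and 1.83 (SE 0.32) for Thy1. Neither passed the threshold over all genes (limma adjusted p of 1 and 0.270), and the exact permutation p of each was 0.1, the smallest that 3 against 3 libraries allow.

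At 10 months neither gene followed the labels. Mapt was at 42.6, 12.4 and 3.31 FPKM in the libraries labelled transgenic and at 42.7, 8.13 and 9.08 FPKM in those labelled control, with a log2 fold change of -0.28 (SE 0.85, limma adjusted p = 1, exact permutation p = 0.9). Thy1 was at 172, 114 and 159 FPKM against 115, 314 and 176 FPKM, with a log2 fold change of -0.34 (SE 0.32, limma adjusted p = 0.969, exact permutation p = 0.4). The sign for Mapt turned to 0.49 without the 10-month control 1 library and to 0.64 without the 10-month transgenic 3 library, and that for Thy1 to 0.04 without the 10-month control 2 library. The direction of each 10-month genotype difference below rests on the labels, which the levels of Mapt and Thy1 did not follow.

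**Figure D1:**
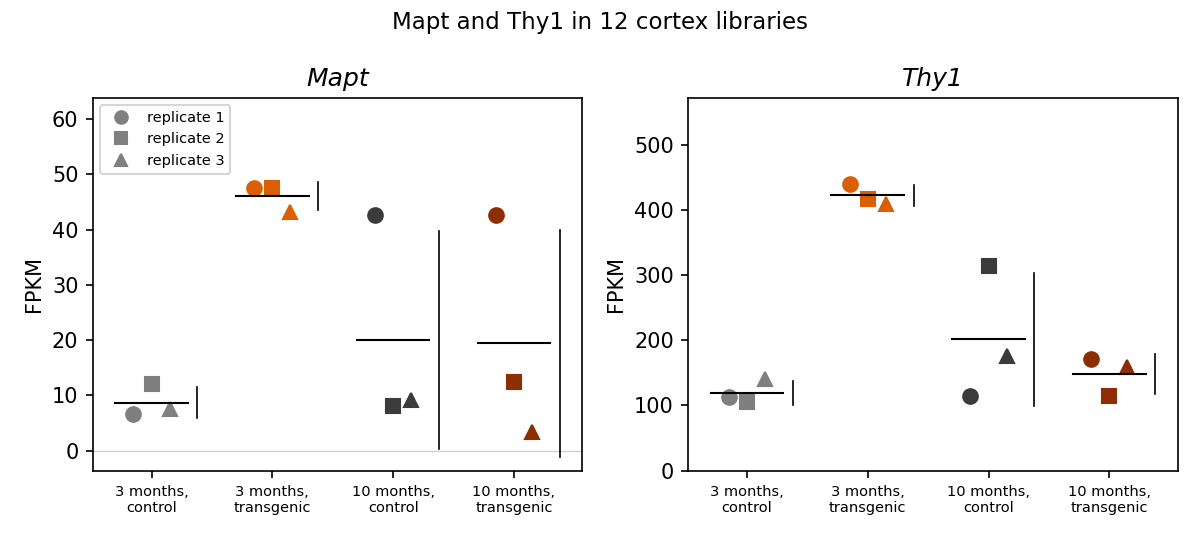
FPKM of Mapt (left) and Thy1 (right) in each library, by age and genotype label, on linear axes. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), horizontal lines are group means and vertical bars 1 SD (n = 3). At 3 months the points labelled transgenic lie above all control points in both panels, and at 10 months the groups overlap.

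At 10 months, cytosolic chaperone genes were lower as a group in the libraries labelled transgenic, while genes of myelinating oligodendrocytes and of MHC class II were higher as groups, by camera at a preset inter-gene correlation and not with an estimated correlation (adjusted p = 0.715 for each list). Of the 10 splits of the 10-month libraries, 3, the real one included, gave at least 3 lists by camera at the preset correlation (highest other 4). This number of lists therefore does not set the labels apart from other groupings. Of the 15 chaperone genes measured, 13 had negative fold changes (median log2 fold change -0.47; camera adjusted p = 0.00267, and adjusted p = 0.715 with an estimated correlation). Dnaja1, an Hsp40 co-chaperone of Hsp70, was at 14.4 ± 1.59 against 31.4 ± 14.4 FPKM (SD, n = 3). Hsph1, an Hsp110 nucleotide exchange factor, had a log2 fold change of -0.61 (SE 0.26). Hspb1, a small heat shock protein, was at a log2 fold change of -0.79 (SE 0.37), and Hspa1a, the inducible Hsp70, at 0, 3.17 and 5.16 FPKM against 13.1, 6.37 and 5.25 FPKM. None of the 15 passed over all genes or adjusted over the list alone. The list's adjusted p was 0.244 without the 10-month control 1 library and 0.131 without the 10-month transgenic 1 library, which held 11228 FPKM of the pituitary hormone Gh, within a range of 6.91e-05 to 0.244 over the libraries left out in turn.

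Of 15 oligodendrocyte and myelin genes, 11 had positive fold changes (median 0.25; camera adjusted p = 0.0497, and adjusted p = 0.715 with an estimated correlation). Opalin, a membrane protein of oligodendrocytes, was at 8.23, 5.73 and 10.3 FPKM in the libraries labelled transgenic against 1.66, 1.75 and 1.43 FPKM (log2 fold change 2.23, SE 0.50). It did not pass over all genes (limma adjusted p = 0.969) and passed adjusted over the list alone (adjusted p = 0.0180), the only member to do so. Mag, the myelin-associated glycoprotein, had a log2 fold change of 1.07 (SE 0.38), Ermn, a cytoskeletal protein of myelinating cells, of 2.05 (SE 1.08), and Mal, a myelin proteolipid, of 0.30 (SE 0.22). Gjb1, a gap junction gene of the same list, was at -2.20 (SE 1.99). The list stayed past the threshold in 2 of 12 fits that left out a library, those without the 3-month control 2 or the 10-month control 1 library, and its adjusted p ranged from 0.00816 to 0.267. Of 8 other alternatives, 6 ended the call, among them a pseudocount of 1 (adjusted p = 0.0513) and quantile normalization (0.0722), within a range of 0.00398 to 0.715.

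All 5 MHC class II genes measured, whose products present antigen on macrophages, microglia and other immune cells, had positive fold changes (median 1.91; camera adjusted p = 0.0497, and adjusted p = 0.715 with an estimated correlation). H2-Aa was at 4.10, 0.586 and 0.672 FPKM in the libraries labelled transgenic against 0, 1.06 and 0 FPKM. H2-Ab1 was at 2.88, 0.489 and 0.799 against 0, 0.556 and 0.238 FPKM, and H2-Eb1 at 5.82, 0 and 1.72 against 0, 1.95 and 0 FPKM. H2-DMa was at 4.30, 0.755 and 0.896 against 1.19, 0.646 and 0.849 FPKM. None passed over all genes or adjusted over the list alone. The highest value of each of these 4 genes was in the 10-month transgenic 1 library, which also held 11228 FPKM of Gh and 1482 FPKM of Prl, hormones of the pituitary gland. Without that library fewer than 3 of the genes could be tested, and the list's call held in 2 of the 11 other fits that left out a library, those without the 10-month control 2 or the 10-month transgenic 2 library, with adjusted p from 0.00268 to 0.306. Of 7 other alternatives, 4 ended the call (range 0.0320 to 0.715).

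No other list passed at 10 months. The nearest, each at a camera adjusted p of 0.116, were postsynaptic genes (10 of 15 negative), interferon response genes (4 of 4 positive) and marker genes of the thalamus (3 of 3 negative). Disease-associated microglia genes, a signature of microglia around protein deposits, had an adjusted p of 0.295, homeostatic microglia genes of 0.921, A1 reactive astrocyte genes of 0.328, excitatory neuron genes of 0.328 (11 of 13 negative, median -0.43), and genes of tau and other microtubule proteins of 0.498. Limma's fry called 0 of 35 lists (smallest adjusted p 0.572). Over all lists, 0 members passed over all genes and 3 passed adjusted over the list alone, Opalin and 2 genes of MHC class I and antigen processing. These were Tapbp, at 0.0166, 0.355 and 0.130 against 1.89, 1.49 and 2.30 FPKM, and H2-Q4, at 1.93, 0.548 and 0.848 against 0, 0.176 and 0 FPKM.

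Of single genes at 10 months, 1 of 9846 passed the threshold. Klhl23 (ENSMUSG00000042155, chromosome 2, 69821944 to 69836651, plus strand), which encodes a protein of the kelch family, was at 1.51, 2.27 and 1.73 FPKM in the libraries labelled transgenic and listed at 0 in the 3 labelled control (limma adjusted p = 0.0139). No gene was lower past the threshold. At an unadjusted p under 0.05 there were 433 genes, 225 higher and 208 lower, against 492.3 given by chance, and 8.26% of genes had groups that did not overlap, against 10% by chance. Leaving out any 1 of the 12 libraries moved the count, to between 0 and 8. The limma adjusted p of Klhl23 was 0.0583 without the 3-month transgenic 2 library and 0.0556 without the 3-month transgenic 3 library (range 0.00873 to 0.0583). It was 0.611 with a pseudocount of 1 and 0.104 with the replicate block (range 8.11e-07 to 0.611 over the other alternatives). With only the 6 libraries of that age, 0 genes passed.

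At 3 months, 4 genes passed the threshold, 1 higher and 3 lower in the libraries labelled transgenic. Pfdn5 (ENSMUSG00000001289, chromosome 15, 102326116 to 102331873, plus strand) encodes a subunit of prefoldin, which hands newly made actin and tubulin to a chaperonin. It was lower, at 5.32 ± 0.807 against 93.9 ± 15.1 FPKM (SD, n = 3), a log2 fold change of -4.11 (SE 0.26, limma adjusted p = 0.000218). The other 3 are processed pseudogenes. Tcea1-ps1 (ENSMUSG00000067869, chromosome 15, 90882615 to 90883518, plus strand) was at 9.80, 11.2 and 9.60 FPKM in control libraries, and Gstm2-ps1 (ENSMUSG00000107369, chromosome 5, 116632908 to 116633564, minus strand) at 9.21, 10.3 and 9.37 FPKM. Both were listed at 0 in the 3 libraries labelled transgenic (limma adjusted p = 0.00129 each). The predicted gene Gm9493 (ENSMUSG00000044424, chromosome 19, 23619749 to 23620319, plus strand) was at 23.1, 18.4 and 19.5 FPKM in the libraries labelled transgenic and listed at 0 in those labelled control (limma adjusted p = 0.000448). The pseudogenes share between 54.1% and 83.7% of their 31-base words with the closest gene, so their values are uncertain.

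These 4 genes passed in each of the 12 fits that left out a library. For the pseudogenes such fits test little, since each is listed at 0, without spread, in every library outside 1 group. The count rose to between 7 and 12 without any 1 of the 3-month libraries or the 10-month control 3 library. At an unadjusted p under 0.05 there were 334 genes, 172 higher and 162 lower, against 492.3 by chance, and 7.98% of genes had groups that did not overlap, against 10% by chance.

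**Figure D2:**
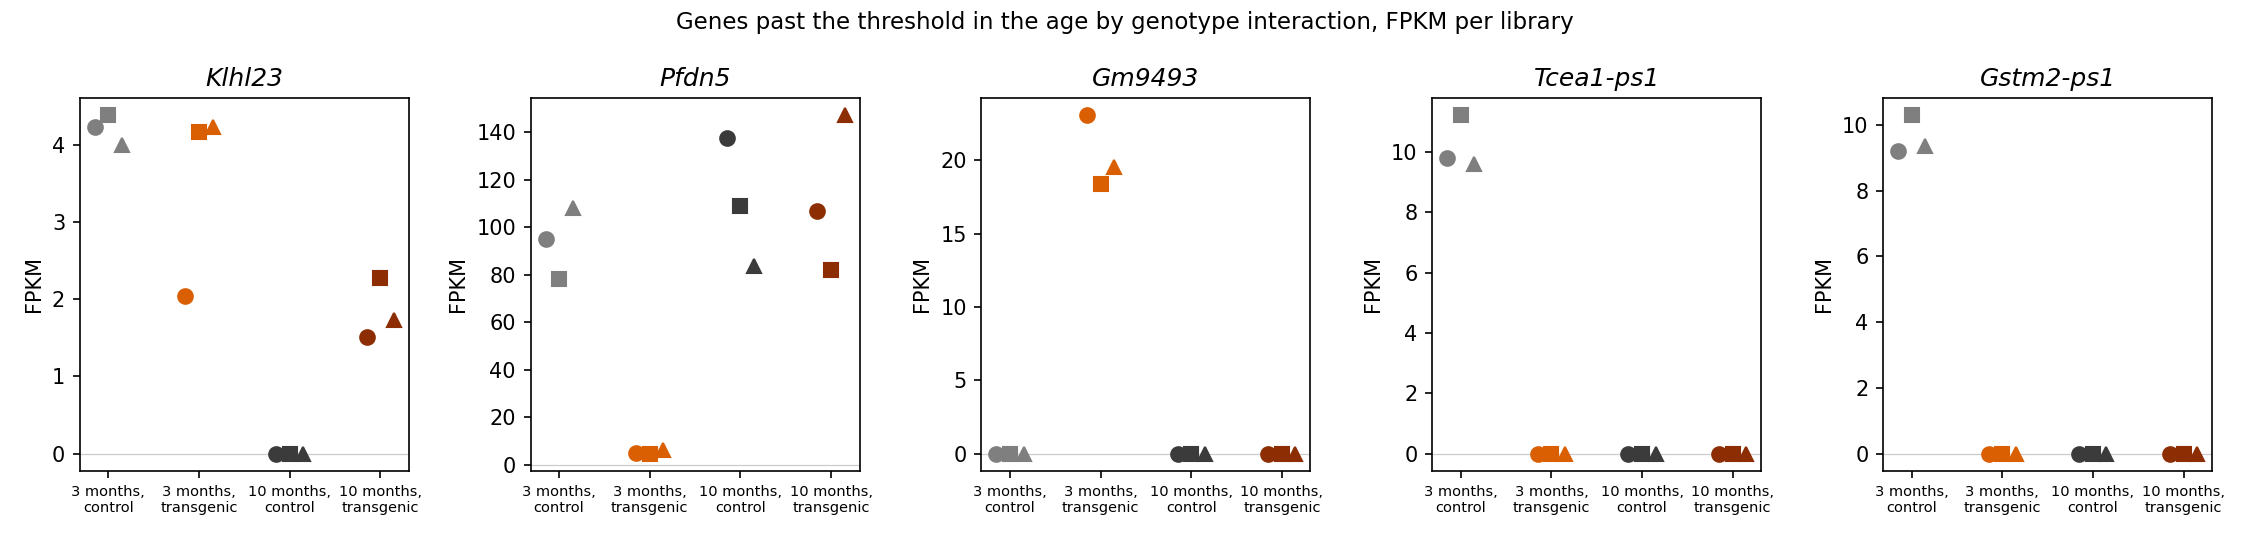
FPKM per library of the 5 genes past the threshold in the age by genotype interaction, 1 panel per gene, on linear axes with their own scales. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), grouped by age and genotype label. Klhl23 is listed at 0 in the 10-month control libraries, Pfdn5 is low in the 3-month libraries labelled transgenic, Gm9493 is above 0 in those alone, and Tcea1-ps1 and Gstm2-ps1 are above 0 in the 3-month control libraries alone.

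Hemoglobin genes were higher as a group at 3 months in the libraries labelled transgenic (4 of 4 positive, median log2 fold change 1.87; camera adjusted p = 0.00133, and adjusted p = 0.998 with an estimated correlation). Hba-a1 was at 32.7 ± 24.5 against 6.30 ± 2.53 FPKM (SD, n = 3), a log2 fold change of 2.18 (SE 0.58). It did not pass over all genes (limma adjusted p = 0.914) and passed adjusted over the list alone (adjusted p = 0.0156). Hba-a2 was at 3.21, 22.9 and 22.6 against 4.24, 5.29 and 2.80 FPKM, Hbb-bs at 8.75, 33.4 and 15.6 against 7.48, 3.96 and 7.36 FPKM, and Hbb-bt at 8.51, 24.8 and 22.6 against 4.25, 0 and 8.01 FPKM. Each was highest in the 3-month transgenic 2 library, which held 37.4 FPKM of Gh. The list's adjusted p was 0.0571 without that library, the highest of the 12 fits that left out a library (lowest 0.000184). Of the 10 splits of the 3-month libraries, 5, the real one included, gave at least 1 list by camera at the preset correlation (highest other 3). All other lists had a camera adjusted p of 0.998, fry called 0 lists (smallest adjusted p 0.981), and Hba-a1 was the only list member past the threshold adjusted over the list alone.

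**Figure D3:**
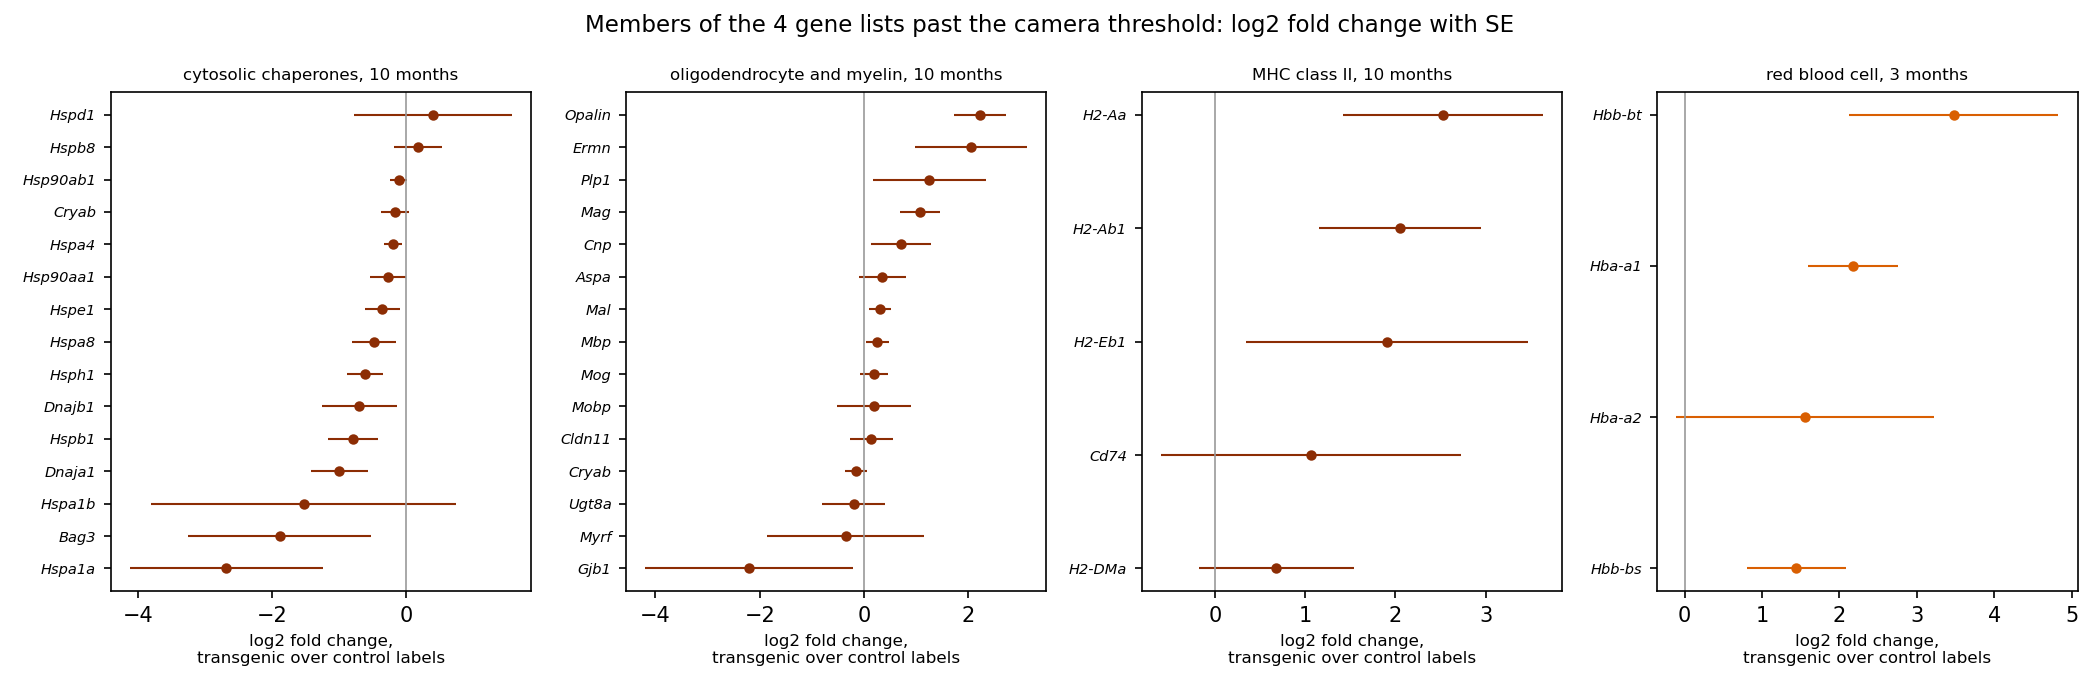
Log2 fold changes (log2(FPKM + 0.1) scale, linear axis) of the members of the 4 gene lists past the camera threshold, libraries labelled transgenic over control. Points are fitted values and bars 1 SE from the model of all 12 libraries; the first 3 panels are at 10 months and the last at 3 months. Most chaperone genes lie below 0, and all MHC class II and hemoglobin genes lie above 0; estimates of genes listed at 0 in a library depend on the pseudocount.

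The age by genotype interaction passed the threshold for 5 genes (4 positive and 1 negative). They were the 5 called within an age. Gm9493, Tcea1-ps1 and Gstm2-ps1 were listed at 0 in all 10-month libraries, so their interaction only repeats the 3-month difference with its sign reversed. Age and deposited table are the same split of the libraries, so whether age or the table set these values at 0 cannot be told. The 10-month minus 3-month difference for Pfdn5 was 4.13 on the log2 scale (SE 0.37, limma adjusted p = 0.00561), since at 10 months it was at 112 ± 33.0 FPKM in the libraries labelled transgenic and 110 ± 27.0 FPKM in the control libraries (SD, n = 3). Limma adjusted p values were 0.0115 for Gm9493, 0.0303 for Tcea1-ps1 and for Gstm2-ps1, and 0.0315 for Klhl23. At an unadjusted p under 0.05 there were 327 genes against 492.3 by chance. Pfdn5 passed in all 12 fits that left out a library, Gm9493 in 10 and Tcea1-ps1, Gstm2-ps1 and Klhl23 in 4 of them; the count ranged from 2 to 11. The interactions of Mapt (-2.72, limma adjusted p = 0.987) and Thy1 (-2.17, limma adjusted p = 0.620) did not pass. No gene list passed with camera (smallest adjusted p 0.139, cytosolic chaperones), with an estimated correlation or with fry, so the list differences within an age are not shown to differ between the ages.

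No gene was called at both ages in the same direction. The overlap was 0 genes against 0.000102 expected (Fisher's exact test, two-sided p = 1). Across the 9846 genes, which are not independent replicates, the log2 fold changes at the 2 ages had a Pearson r of 0.0175 and a Spearman rho of 0.0162.

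With age, 3 genes were lower in the 10-month than in the 3-month control libraries and 0 were higher. Klhl23 was at 4.22, 4.38 and 4.00 FPKM at 3 months and listed at 0 in all 3 at 10 months (limma adjusted p = 0.00142). Tcea1-ps1 and Gstm2-ps1 were also listed at 0 at 10 months (limma adjusted p = 0.00173 each). At an unadjusted p under 0.05 there were 413 genes, 251 higher and 162 lower, against 492.3 by chance, and 10.1% of genes did not overlap, against 10% by chance. These 3 genes passed in all 12 fits that left out a library, in which the count ranged from 3 to 10. For Tcea1-ps1 and Gstm2-ps1 such fits test little, since both are listed at 0 outside the 3-month control libraries. In the libraries labelled transgenic, Pfdn5 was higher at 10 than at 3 months (log2 fold change 4.34, SE 0.26, limma adjusted p = 0.00013) and Gm9493 was listed at 0 in all 3 at 10 months (limma adjusted p = 0.000448). There were 424 genes at an unadjusted p under 0.05, 231 higher and 193 lower, and 9.43% of genes did not overlap. Both genes passed in all 12 fits that left out a library, with counts from 2 to 13. For Gm9493 such fits test little, since it is listed at 0 outside the 3-month libraries labelled transgenic. Age and deposited table are the same split of the libraries, so an age effect cannot be told from a difference between the tables.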

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

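The tests of switching between levels and of shared sequence in this part were chosen after the results were seen; the interaction and the redrawn label splits were planned. Pfdn5, Klhl23, Gm9493, Tcea1-ps1 and Gstm2-ps1 stood out because their genotype effects at 3 and at 10 months differed in a test of the difference itself. The 10-month minus 3-month difference on the log2(FPKM + 0.1) scale was 4.13 for Pfdn5 (limma adjusted p = 0.00561), 4.59 for Klhl23 (0.0315), -7.67 for Gm9493 (0.0115), 6.68 for Tcea1-ps1 (0.0303) and 6.60 for Gstm2-ps1 (0.0303). For the last 4 the size is set by the pseudocount, since a whole group is listed at 0. Gm9493, Tcea1-ps1 and Gstm2-ps1 are listed at 0 in all 10-month libraries, so their difference only repeats the 3-month effect. When the labels were redrawn within each age, 35 of 100 label sets, the real one included, gave at least its 5 interaction genes, with up to 12 in another set, so chance is not excluded as a source of this number of genes.

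In Pfdn5, Gm9493, Tcea1-ps1 and Gstm2-ps1 each library sits at one of a pair of levels, with the 3 libraries of a group at the same level; Klhl23 is listed at 0 in the 10-month controls and lies between 1.51 and 4.38 FPKM elsewhere. Shared sequence as the whole source of the change was argued against for Pfdn5, where the highest values of the annotated genes that share at least 5% of its 31-base words sum to 7.11 FPKM against a difference of 88.5 FPKM, and for Klhl23, where no gene shares as many, against 1.84 FPKM. Tcea1-ps1 shares 82.6% of its words with Tcea1, which is listed at 0 in every library. The other genes that share at least 5% of them reach at most 0.079 FPKM, so the listed values hold no counterpart to its change. A value listed at 0 does not show that Tcea1 is unexpressed, so shared reads are not decided for Tcea1-ps1. Gstm2-ps1 shares 54.1% of its words with Gstm1, and Gm9493 83.7% with Rps7. For these 2, shared sequence cannot be told apart from a change in expression, because Gstm1 and Rps7 vary by more than the pseudogenes hold. Switching between levels without regard to genotype is not excluded as a source of the calls. Of the 1836 genes with such levels, 226 were at the higher level in 3 of the 6 10-month libraries. Of these, 7.08% followed the labels (exact binomial p = 0.182 against 10%), and at 3 months 13.4% of 209 did (exact binomial p = 0.106). The test takes genes of the same libraries as independent and can count the called genes too, so its p-values do not decide the question. A genotype effect that differs with age stays open and untested beyond these values.

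Other splits of the 6 libraries within a comparison are too few, at 10, for a share under 0.05. For the genotype effect at 10 months, 9 splits, the real one included, gave at least its 1 gene, and the highest other gave 6. For the genotype effect at 3 months, 4 splits gave at least 4 genes (highest other 6). For the age effect in controls 5 splits gave at least 3 genes (highest other 6), and for the age effect in libraries labelled transgenic 7 gave at least 2 (highest other 9). For the gene lists, 3 splits gave at least 3 lists at 10 months (highest other 4) and 5 gave at least 1 list at 3 months (highest other 3). Splits with several times the real count, such as 9 genes against 2 with age and 6 against 1 at 10 months, may point to a structure of the samples, for which no test was made. The 10-month transgenic 3 library had the lowest median correlation with its own group (0.672) and the most tested genes listed at 0 (1067). Without it the counts were 6 at 10 months and 13 for the age effect in libraries labelled transgenic. Without the 10-month control 3 library they were 8 and 4. For the overlap between ages and the lists of the interaction the real count is 0, which every redrawn label set reaches, so the redraws test neither; the highest others were 2 genes and 6 lists. In the interaction, 4 of 35 lists had an unadjusted camera p under 0.05 and 0 lists passed with fry.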

How the results depend on the processing

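Robust regression, values set to missing and the Alad alternatives were added after the data were seen. Of single genes, Pfdn5 kept its calls at 3 months, in the interaction and with age in the libraries labelled transgenic under every alternative that tested it, and Mapt and Thy1 at 3 months kept their direction. Median-of-ratios and quantile scaling left the 5 counts of genes as they were. No cause was tested except where named.

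For the genotype effect at 10 months (1 gene), the count was 2 without the filter and 0 with the filter at 5 FPKM, which does not test Klhl23, with only the 6 libraries of that age, and with values under 0.25 of the gene's median set to missing. For the genotype effect at 3 months (4), it was 9 without the filter, 2 at 5 FPKM, 14 with only the 6 libraries of that age (6 higher, 8 lower) and 0 with values set to missing. For the age by genotype interaction (5), it was 2 with pseudocount 0.01, 9 without the filter, 1 at 5 FPKM and 0 with values set to missing. For the age effect in controls (3), it was 7 without the filter, 0 at 5 FPKM and 0 with values set to missing. For the age effect in transgenic mice (2), it was 7 without the filter, 6 with eBayes without trend and robust, and 1 with values set to missing. Setting values to missing removes the low level of each such gene, and the filter at 5 FPKM tests 5271 genes.

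Robust regression in place of least squares gave 574 genes at 10 months, 489 at 3 months, 588 for the interaction, 551 for the age effect in controls and 550 for the age effect in transgenic mice. It gives less weight to a library that departs from the rest of its group, and the SE of Mapt was 0.24 against 0.85. It kept 1 of the 4 calls at 3 months, 2 of 5 in the interaction and 1 of 3 in controls; for Tcea1-ps1 and Gstm2-ps1 its SE was 92232.6 and 22421.2 and each call was lost (limma adjusted p = 1), so its standard errors are not usable for such genes. Under it Mapt at 3 months passed the threshold at 2.49 and Thy1 at 1.84, and Mapt at 10 months reversed to 0.32. At 10 months it also brought Opalin (limma adjusted p = 0.00218), Ermn (0.00145) and Dnaja1 (0.0185) past the threshold. The groups of Ermn and Dnaja1 overlap. Ermn was at 14.2 FPKM in the 10-month control 1 library and Dnaja1 at 15.3 FPKM in the 10-month control 3 library, within the range of the libraries labelled transgenic. The SE of Ermn was 0.31 against 1.08. No labels were redrawn under robust regression, so how many genes it calls without a genotype difference is unknown. Mapt at 10 months also reversed with limma arrayWeights per library, to 0.67.

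Of the fixed gene lists at 10 months (3), 0 passed with the inter-gene correlation estimated per list, and 1 each with pseudocount 0.01 and without the filter. Of the fixed gene lists at 3 months (1), 0 passed with it estimated. Of the fixed gene lists in the age by genotype interaction (0), 1 passed with a group mean FPKM of at least 5 and 1 with quantile normalization of log2 values. MHC class II had too few tested genes at 5 FPKM and without the 10-month transgenic 1 library.

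Leaving out each library in turn gave 0 to 8 genes at 10 months, 4 to 12 at 3 months, 2 to 11 for the interaction, 3 to 10 for the age effect in controls and 2 to 13 for the age effect in transgenic mice. Lists ranged from 1 to 3 at 10 months, 0 to 2 at 3 months and 0 to 2 for the interaction. For the genotype effect at 10 months and at 3 months, Mapt ranged from -1.18 to 0.64 at 10 months, with 0.49 without the 10-month control 1 library, and from 2.27 to 2.69 at 3 months. Thy1 ranged from -0.69 to 0.0400 at 10 months and from 1.74 to 1.95 at 3 months, where it passed without the 10-month control 2 library (limma adjusted p = 0.0339). H2-DMa (0.68) in the genotype effect at 10 months reversed to -0.0746 without the 10-month transgenic 1 library and was 1.11 without the 10-month transgenic 2 library. Alad, averaged over both ages, stayed between 1.06 and 1.22 and past the threshold in 5 of 12 fits (limma adjusted p from 0.0281 to 0.0965). Of its 11 other alternatives 2 ended the call, the replicate block (0.166) and eBayes without trend and robust (0.0637), within a range of 1.07e-05 to 0.166.

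The replicate numbers share only a number between groups: correlations of deviations in the 18 same-number pairs lay between -0.123 and 0.0939, and 2 of the 12 libraries correlated best with a library of their own number (0 when only libraries of the same age were compared). With the replicate block, 0 genes passed at 10 months, 1 in the interaction and 1 list at 10 months; the other counts moved by under 1.5 times. The fits without a library keep at least 2 per group. Depth is unknown in absolute terms, so it cannot be said which values of 0 it limits.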

Other observations

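In this part, the effects averaged over both genotypes or both ages, the list tests of the age effects, the pituitary genes, and the tests of library labels, of level switching, of the Alad region and of a duplication were chosen after results were seen. With age, 4 lists of immune and activity genes passed in the libraries labelled transgenic by camera at a preset inter-gene correlation, and 0 of them with an estimated correlation (adjusted p between 0.618 and 0.622). From 3 to 10 months, 5 of 5 MHC class II genes (median log2 change 2.58) and 5 of 5 A1 reactive astrocyte genes (1.07) had positive changes, both lists at a camera adjusted p of 0.00945, and 0 members of any list passed over all genes. Each MHC class II gene was highest in the 10-month transgenic 1 library (H2-Aa 4.10, H2-Eb1 5.82 and Cd74 7.17 FPKM), which also held 11228 FPKM of the pituitary hormone Gh. Of 17 disease-associated microglia genes, 12 had positive changes (median 0.35, adjusted p = 0.0140), among them Axl (1.19, SE 0.32), a receptor of phagocytes, and Spp1 (1.77, SE 0.66), osteopontin. Of 17 immediate early genes, which follow neuronal activity, 12 had negative changes (median -0.93, adjusted p = 0.0140), with Egr2 at -1.70 (SE 0.46). In all, 0 lists passed in the control libraries (camera, smallest adjusted p 0.190, with 5 lists at an unadjusted p under 0.05; fry, 0 lists), and the interaction of no list passed, so a difference between genotypes is not shown. Adjusted over the list alone, H2-D1, H2-Aa, H2-Ab1 and H2-Q4 passed higher in the libraries labelled transgenic. C1qc, a complement gene (log2 change -2.14, SE 0.43), and Tapbp, of antigen processing (-2.78), passed lower. For C1qc the limma p adjusted over the list alone was 0.00271, and the adjusted p over all genes 0.477.

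Averaged over both genotypes, 3 lists passed with age by camera and 0 with an estimated correlation (adjusted p = 0.612 for each). Of the immediate early genes 15 of 17 had negative changes (median -0.59, camera adjusted p = 0.00622), and 5 of 5 A1 reactive astrocyte genes and 4 of 5 MHC class II genes had positive changes (camera adjusted p = 0.0169 each); 0 members passed over all genes. For genotype averaged over both ages, 1 list passed, red blood cell genes (4 of 4 positive, camera adjusted p = 0.0305; adjusted p = 0.840 with an estimated correlation). Single genes added by the age effect averaged over both genotypes were Gm5424, a processed pseudogene, at 8.01 ± 0.909 and 8.22 ± 0.271 FPKM in the 10-month control and transgenic libraries against 4.04 ± 0.219 and 4.49 ± 0.110 FPKM at 3 months (SD, n = 3; log2 change 0.91, SE 0.12, limma adjusted p = 0.0316). Gm10116 was listed at 0 in the 6 libraries of 3 months and between 0.862 and 1.41 FPKM at 10 months (limma adjusted p = 0.0202), and Rpl18-ps2 was at most 0.114 FPKM at 3 months and between 0.704 and 2.95 FPKM at 10 months (limma adjusted p = 0.0429). Gm5424 shares 84.7% of its 31-base words with Ass1, and Rpl18-ps2 76.9% with Rpl18. Cabp7, which encodes a neuronal calcium-binding protein and was singled out after its values were seen, was at 12.2, 8.40 and 10.9 FPKM in the 10-month libraries labelled transgenic and between 0.577 and 1.92 FPKM in the other 9 libraries. It did not pass (log2 fold change 3.07, SE 0.44, limma adjusted p = 0.194).

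Pituitary hormone genes were at high levels in the 10-month transgenic 1 library alone. Gh was at 11228 FPKM there, Prl at 1482, Pomc at 547, Cga at 158 and Lhb at 54.0 FPKM. In the 3-month transgenic 2 library Gh was at 37.4, Prl at 10.0 and Pomc at 5.11 FPKM, and in the other libraries Gh was at 14.8 FPKM or less. Of the 14 genes of the list, Chgb was also expressed in the other libraries, at 23.4 to 216 FPKM. Ttr, abundant in choroid plexus, ranged from 5.24 to 728 FPKM over the 12 libraries, with 728 FPKM in the 3-month control 1 library.

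Mapt and Thy1 parted the labels at 3 months and not at 10 months. If transgenic libraries keep the 3-month levels of both genes at 10 months, an exchange of labels among the 10-month libraries and nothing else is argued against. Of the 6 libraries, 0 lay above the midpoints of the 3-month groups in both genes (22.8 FPKM for Mapt, passed by 2 libraries, and 240 FPKM for Thy1, passed by 1). If these genes switch between levels without regard to genotype, the midpoints cannot speak to an exchange. Of the 4390 expressed genes, 11.9% spanned at least the 12.9-fold range of Mapt over the 10-month libraries, and 38.6% the 2.76-fold range of Thy1. Such a range measures spread and not a pair of levels, so it cannot decide whether switching gave the 10-month values. At 3 months, 1.05% of the expressed genes parted the labels by at least as much as Thy1, in either direction, against a median of 1.14% in other splits (highest 1.37%). For a single gene chosen beforehand, as Thy1 was, a share of 1.05% is small. The like share in other splits describes expressed genes at large and does not decide for Mapt and Thy1. Mapt also reached 42.7 FPKM in the 10-month control 1 library and 42.6 FPKM in the 10-month transgenic 1 library. Whether switching gave the 3-month difference of either gene is not decided by these values. Loss of transgene expression with age, transgene reads that the quantification left uncounted, and samples from outside this series stay open and untested.

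Alad, which encodes the heme synthesis enzyme aminolevulinate dehydratase (chromosome 4, 62509169 to 62519918, minus strand), was higher in the libraries labelled transgenic at both ages, at 13.3 ± 1.78 against 5.98 ± 0.419 FPKM at 3 months and 17.3 ± 4.25 against 7.41 ± 0.332 FPKM at 10 months (SD, n = 3). Averaged over both ages the log2 fold change was 1.16 (SE 0.14, higher in 6 of 6 libraries, limma adjusted p = 0.0242), with an exact permutation p of 0.005 over 400 arrangements within ages, the smallest they can give; its call was lost in 7 of 12 fits that left out a library and in 2 of 11 other alternatives (limma adjusted p from 1.07e-05 to 0.166 over the latter). The 8 tested neighbours within 1 Mb had a median log2 fold change of -0.48 (SD 0.82), and 0 of them reached 0.58. This argues against a raised region of 1 Mb or more unless drops in single libraries lowered their values, which was not tested. A duplication of Alad together with its neighbour Hdhd3, as known in some mouse strains, cannot be told apart from other sources. Hdhd3 was above each control library in 3 of 6 libraries labelled transgenic (5.23 to 6.48 FPKM) and below each in the other 3 (0.162 to 0.377 FPKM). Chance could give such a gene: 35 of 100 label sets, the real one included, had at least the 24 genes that part the labels at both ages by 1 on the log2 scale (highest other 66), and in 47 of the same 100 a gene that parts them reached the p of Alad, 1.01e-05 (lowest other 1.02e-12). An effect of the transgene or of its insertion site stays open and untested.

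In the authors' deposited table, 1 of 19247 tested genes had a q under 0.05 at 10 months (Gm44510, log2 fold change 0.58) and 3 of 19196 at 3 months (Gstm2-ps1, Tcea1-ps1 and Dhx8). Pfdn5 had an authors' q of 0.141 at 3 months and Klhl23 of 0.577 at 10 months. Mapt and Thy1 had authors' log2 fold changes of 2.18 and 1.87 at 3 months (q of 0.404 and 0.422) and of 0.34 and -0.33 at 10 months (q of 0.934 and 0.894), where the sign for Mapt is opposite to the -0.28 found here.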
